A study of Drosophila melanogaster with 12 samples.

How the data were processed

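Stage 14 follicles of Drosophila melanogaster, the mature egg chambers of the ovary, were sampled from the Oregon R stock, a common wild-type stock, at time points labelled day 2 and day 12. Per the labels, RNA was extracted with Trizol, libraries were made with a standard Illumina procedure, and 12 libraries were sequenced: 3 for linear RNA and 3 for circular RNA (circRNA, joined head to tail by back-splicing) at each day. The labels number biological replicates 1 to 3 within each group, and give no batch, depth, read length, strandedness or starting point of the day count. Groups were taken from the sample titles.

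Per the submitters' processing notes, HISAT2, StringTie, STAR and DESeq2 were used with genome build dm6. Versions, the role of each tool, the library selection and the annotation are not given in the sources used here. For each kind of RNA the authors deposited a table with 1 signal value per day, which the file headers assign to 3 libraries together. Values of single libraries were not used here, so no SD, no replicate test and no left-out library could be had. All p-values per transcript or circRNA come from the authors' deposited tables, and the test behind them is not given in the sources used here.

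The linear RNA table lists 10162 transcripts of 5954 gene identifiers: 7490 annotated and 2672 assembled by the authors. The signal values the authors deposited for transcripts are abundances, and 3 times each value is whole at 6 decimals, as for a mean of 3 numbers. Whether they are FPKM or TPM is not stated. Listed values sum to 628567 at day 2 and 634242 at day 12. The higher of the 2 means of each listed transcript was at least 0.683. The authors' deposited log2 fold change equals the log2 ratio of the 2 means with no pseudocount, so it has no finite value for the 339 transcripts with a mean of 0 on 1 day. The deposited adjusted p-value equals a Benjamini-Hochberg adjustment over the listed transcripts. The authors' significance mark in the transcript table follows the unadjusted p under 0.05, and in the circRNA table the adjusted p under 0.05. Throughout, a transcript or circRNA was called at an adjusted p under 0.05.

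The circRNA table lists 2747 circRNAs by number, with no position or host gene. In the signal values the authors deposited for circRNAs, every day 12 value was a whole multiple of 17.8, within a relative tolerance of 1e-06 of a step, with a lowest value of 3 steps. Every day 2 value was a whole number of these steps plus a whole number of a second step of 19.1, with 1 solution each. The pattern is that of scaled reads with 1 added per library, with 1 of the 3 day 2 libraries on the first step and 2 on the second. This reading is an assumption: an equal step for 4 libraries is unusual, how the authors scaled is not given in the sources used here, and read totals, read ratios and spreads of circRNAs all rest on it. Where reads are given for circRNAs, they are such steps above the lowest value, and their intervals cover counting error only. They serve to describe how many reads stand behind a value, and no count model was fitted to them. The deposited log2 fold change of circRNAs differs from the log2 ratio of the 2 means by at most 0.02.

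From these tables, the values of all listed transcripts of a gene were summed per day and their log2 ratio taken. Such a sum depends less on how reads were shared among overlapping transcripts. Gene lists were fixed before the data were examined, 31 in all, and 22 had at least 5 measured genes. For each of these, the median log2 change of the gene sums was placed among the medians of 10000 random lists of the same size, each gene replaced by one from the same of 20 bins of mean abundance. Such a percentile describes these means and is not a test across replicates. The number of genes at an unadjusted p under 0.05 was set against the number expected from the same bins. In addition, the authors' p of each list gene's most abundant transcript was adjusted over the list alone by the Benjamini-Hochberg method. Most abundant means the highest mean of both days. Because that p was not recomputed, its direction was read from the ratio of the means. The symbol CCT1, meant for an enzyme of lipid synthesis, is that of a chaperonin subunit in these tables; the lipid list was kept as fixed and also run without it. Coordinates, lengths and gene classes come from Ensembl release 115 of the BDGP6 assembly, whose coordinates are those of dm6; 7468 of the 7490 annotated transcripts were found there.

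The rule for named genes was fixed at the same time as the lists. It took the called transcripts with a mean at or above the median of all called ones, the 2 called members of each list with the largest change, and 13 genes of oocyte and follicle biology whether called or not. Its condition that the libraries of one day all lie above those of the other could not be applied. With 18 called transcripts, the others are named as well. List members that passed only over their list, the small RNA classes and the genes of the closing section were chosen after their values were seen.

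The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. On simulated data, the adjustment matched a reference implementation. Of unshifted random lists of 25 genes, 5% fell outside the 95% range, and all simulated lists shifted by 0.2 (log2) were found, over the 5952 genes of the list step. These lists were drawn at random from the same genes. The check thus does not cover genes that vary together, other list sizes or smaller shifts. The step method returned the reads of 99.3% of 2747 simulated circRNAs with the step sizes first chosen for the simulation, and of 100% with the step sizes of the deposited values, a simulation added after the former result was seen.

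The other settings chosen before the files were opened, as far as the tables allowed them, were a threshold of 0.1, a further condition of a 2-fold change, a minimum mean, a pseudocount of 0.1 and, for circRNAs, a minimum of 2 reads and thinning to equal reads. Others were added after seeing the data. The tests planned for counts or for values of single libraries could not be run on these tables. The comparison of circRNAs with their host genes was left out because the circRNA numbers carry no host.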

Results

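Stage 14 follicles are the end point of Drosophila egg development. Each holds an oocyte arrested in meiosis, loaded with maternal RNA and largely silent in transcription, inside a finished eggshell and a layer of follicle cells, and waits there for ovulation. The series, titled as a study of aging follicles, compared follicles at day 2 with follicles at day 12, for linear RNA and for circRNA, with 3 libraries per day and kind of RNA. Each value below is the authors' mean over the 3 libraries of a day, with no spread, in the authors' own unit. The depth of the linear RNA libraries is unknown. For circRNA, the values correspond to 60601 back-splice reads over the 3 day 12 libraries and 50112 over the 3 day 2 libraries.

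Maternal messages that pattern the embryo were present at similar levels on both days. The germ plasm organiser osk stood at 699 at day 2 and 834 at day 12, and the posterior determinant nos at 755 and 855, in the authors' deposited table. The anterior determinant bcd was at 48.4 and 53.1, and CycB, the B-type cyclin of the meiotic and early embryonic divisions, at 1566 and 1752. Among regulators of maternal translation, Fmr1 was at 76.5 and 78.4 and cup at 34.5 and 28.9. The orb transcript with the highest mean of both days was at 12.3 and 14.7. Another orb transcript went from 22.6 to 0.216 and a further one from 0.196 to 18.7, and the gene summed to 35.1 and 33.6. The Polo inhibitor mtrm, which restrains Polo in the prophase arrest before stage 14, was at 247 and 276. None of these 8 genes was called: their adjusted p ranged from 0.146 for CycB to 0.977 for orb in the authors' deposited table. CycB, osk and mtrm, each slightly higher at day 12, had an unadjusted p of 0.0045, 0.0070 and 0.0368 there. The absence of a call is thus no proof of equal levels. The fixed genes grk, Mmp2 and Cp36 were not analysed here.

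The called transcripts were few. In the authors' deposited table, 18 of 10162 transcripts had an adjusted p under 0.05, of which 10 were higher and 8 lower at day 12. At an unadjusted p under 0.05, the mark the authors used, there were 1629, of which 962 were higher, against 508 if p were uniform. The changes behind this larger number were small, with a median size of 0.22 on the log2 scale, which is 1.16-fold. Over all transcripts the median log2 change was 0.05, and it was 0.08 for the 1018 transcripts with a mean over 100.

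The most abundant called transcript was that of RpS20, a protein of the small ribosomal subunit. It fell from 1883 to 633 (log2 change -1.57, adjusted p = 0.0454 in the authors' deposited table). RpS20 lies at 3R from 20822181 to 20823356 on the plus strand, with 4 exons and a pair of small nucleolar RNA genes within its bounds. Oga, the enzyme that removes O-GlcNAc from proteins, fell from 28.4 to 13.0, and Pi3K59F, the phosphatidylinositol 3-kinase of autophagy and endosomes, from 8.53 to 5.98 (adjusted p = 0.0454 for both in the authors' deposited table). Oga shares 2140 bp of its span with CG3337 of the opposite strand, whose summed value was 21.4 at day 2 and 19.1 at day 12. CG42365, a gene with a single exon at 2R from 21666687 to 21667594, fell from 39.5 to 0.00483, with the lowest adjusted p in the authors' deposited table, 0.000363. Its last 54 bp overlap genes of the opposite strand, among them CG42379, whose summed value was 27.4 at day 2 and 30.2 at day 12. The guide RNA snoRNA:Psi18S-531 fell from 5.59 to 0.952 (adjusted p = 0.0168 in the authors' deposited table). It lies within RpL22 on the same strand, and RpL22 summed to 279 and 248.

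Called increases in genes with 1 listed transcript were small. APC7, a subunit of the anaphase-promoting complex that ends meiotic arrest by degrading cyclins, rose from 87.3 to 98.5 in the authors' deposited table. SAK, the kinase that starts centriole duplication, rose from 29.4 to 34.3, and Nse1, of the Smc5/6 complex of chromosome repair, from 65.5 to 73.0. Their log2 changes were 0.17, 0.22 and 0.16, each with an adjusted p of 0.0454 in the authors' deposited table. Pi3K21B, the regulatory subunit of the kinase below the insulin receptor, rose from 87.4 to 105 by its main transcript and from 106 to 125 in the sum over both of its listed transcripts.

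**Figure D1:**
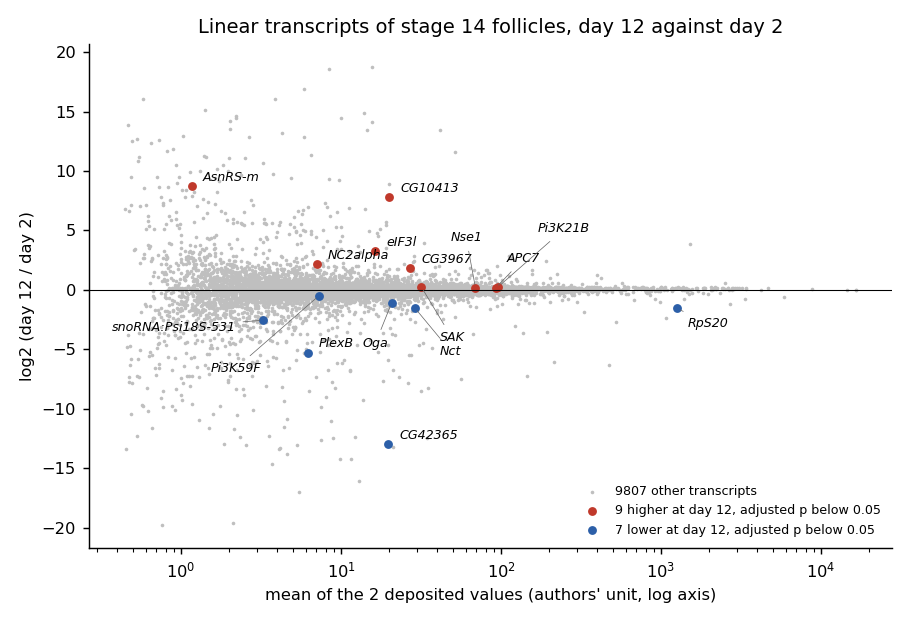
Log2 ratio of day 12 to day 2 against the mean of both days (log axis, authors' unit) for the 9823 linear transcripts above 0 on both days; grey points are single transcripts, red points called increases and blue points called decreases. Of the 18 called transcripts, 16 are drawn, since those of GstT1 and trio were at 0 on 1 day; RpS20 is the most abundant of them.

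Of the 18 called transcripts, 10 belonged to genes with several listed transcripts, and 7 of these genes had a summed change within 0.5 of 0 on the log2 scale. For CG10413 the called transcript rose from 0.182 to 39.9 in the authors' deposited table, while the gene summed to 36.8 at day 2 and 40.1 at day 12. A transcript of GstT1, a glutathione transferase, was listed at 0 at day 2 and 30.9 at day 12, and the gene summed to 122 and 146. For Nct, the nicastrin subunit of gamma-secretase, the called transcript fell from 42.8 to 14.9 and the sum went from 63.8 to 77.0. The called transcript of eIF3l, a subunit of a translation initiation factor, rose from 3.15 to 29.6 in the authors' deposited table, and the sum went from 64.9 to 32.4. The summed log2 changes of NC2alpha, AsnRS-m and trio were 0.26, 0.33 and -0.17, against 2.18 and 8.72 for the called transcripts of the former pair and a listed 0 at day 12 for that of trio. PlexB, a semaphorin receptor, fell by one transcript from 12.1 to 0.305 and went from 26.9 to 16.9 in sum. CG3967, named Atat in the annotation and known as a tubulin acetyltransferase, rose by one transcript from 12.0 to 42.3 and went from 26.2 to 47.8 in sum.

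At the level of genes, most large differences were decreases. Summed values differed at least 2-fold for 155 genes, of which 105 were lower and 50 higher at day 12; with a mean of at least 10 these numbers were 34 and 15. No test across libraries stands behind these counts. Cp15, a chorion protein of the eggshell, went from 254 to 20.8, and CG43134 from 369 to 38.5. RpLP0, a protein of the ribosomal stalk, went from 519 to 144. RpS2, of the small ribosomal subunit, summed to 936 and 32.7. Its most abundant transcript, at 932 and 11.7, had a p of 0.0577 before adjustment in the authors' deposited table. Ilp8, the relaxin-like hormone made by follicle cells of mature follicles, summed to 50.1 at day 2 and 80.1 at day 12, with an unadjusted p of 0.186 for its main transcript in the authors' deposited table.

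**Figure D2:**
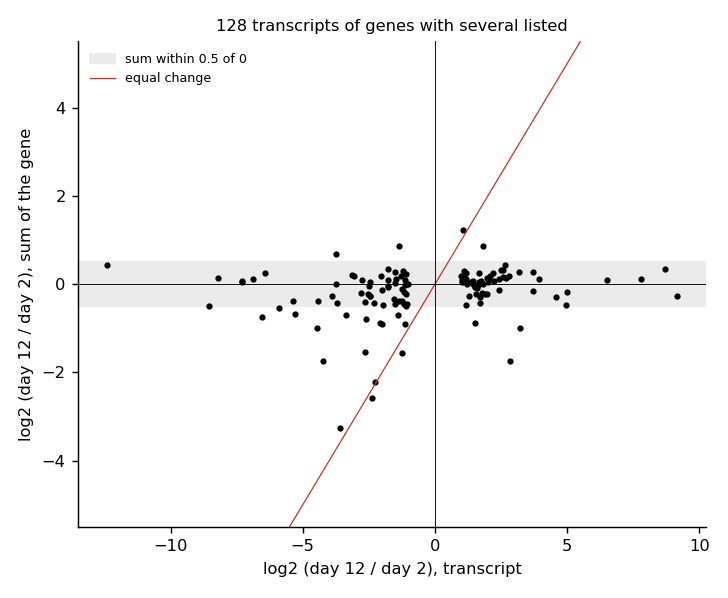
Log2 ratio of day 12 to day 2 of single transcripts (horizontal) against that of the summed value of their gene (vertical), for 128 transcripts of genes with several listed ones, at an unadjusted p under 0.05 and at least a 2-fold change. Each point is 1 transcript; the grey band marks sums within 0.5 of 0 and the red line equal change, and most points lie in the band.

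Transcripts of the mitochondrial genome moved apart by class, with exceptions, and class goes along with length. Of 10 measured mitochondrial mRNAs, 7 fell when the authors' p was adjusted over the list alone: mt:CoI, mt:CoII, mt:CoIII, mt:Cyt-b, mt:ND3, mt:ND4 and mt:ND5, which code for subunits of the respiratory chain. In the authors' deposited table mt:CoI went from 4214 to 2505, mt:CoIII from 3787 to 1640 and mt:ND5 from 203 to 95.8. Of 14 measured tRNAs, 9 rose over the list alone, with log2 changes from 1.22 to 2.36, and mt:tRNA:Asn-GTT went from 1.72 to 8.85. mt:ATPase6 rose from 201 to 2821 in the authors' deposited table. It lies at positions 4062 to 4736 of the mitochondrial genome and shares its last base with mt:CoIII, which runs from 4736 to 5524. The shortest measured mRNA, mt:ATPase8 of 162 nt, went from 9.67 to 14.3 in the authors' deposited table and did not pass over the list alone. None of the 26 mitochondrial RNAs was called over all transcripts, and 17 passed over the list alone. The median log2 change of the list was 0.69, above all of the 10000 random lists. It reflects that the list holds more tRNAs, 13 of 14 higher, than mRNAs, 8 of 10 lower, and describes neither class.

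**Figure D3:**
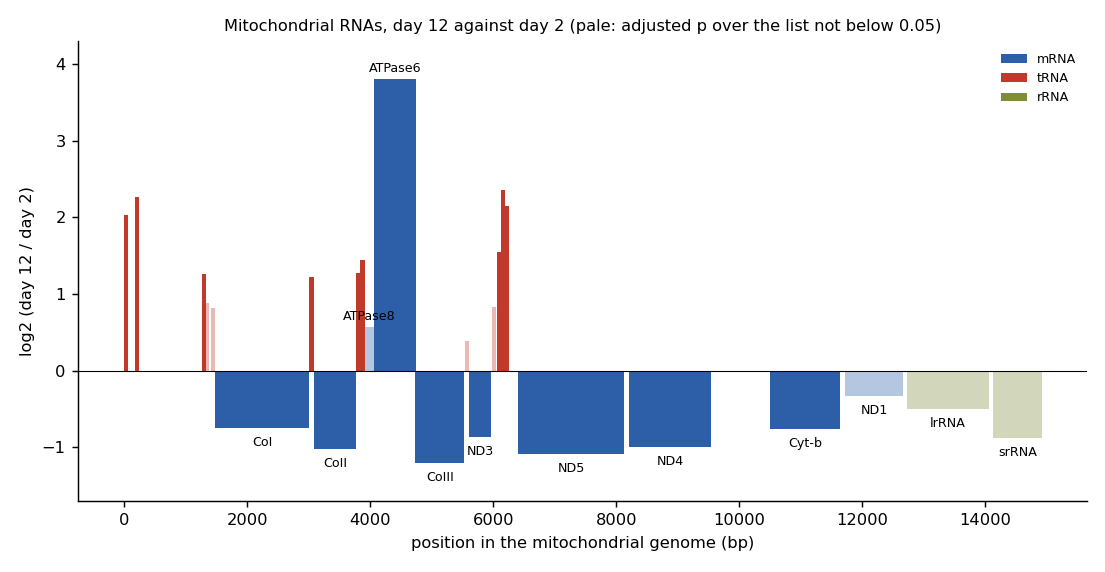
Log2 ratio of day 12 to day 2 (height of the bars) of 25 mitochondrial RNAs at their position in the mitochondrial genome (bp); blue bars are mRNAs, red bars tRNAs and olive bars rRNAs, and pale bars did not pass over the list alone. Bars of mt:CoI, mt:CoII, mt:CoIII, mt:ND3, mt:ND4, mt:ND5 and mt:Cyt-b point down and those of 9 tRNAs and mt:ATPase6 point up.

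Nuclear genes of oxidative phosphorylation were less raised than genes of like abundance. Of 70 measured, 6 fell over the list alone and none rose: ND-75, ND-39 and ND-MNLL of complex I, and ATPsynO, ATPsynB and blw of the ATP synthase. ND-75 went from 23.5 to 14.4, ND-39 from 118 to 86.0 and blw from 261 to 196 in the authors' deposited table. The median log2 change of the list was 0.01, with 36 genes higher and 34 lower, against 0.04 to 0.11 for the middle 95% of matched random lists. An unadjusted p under 0.05 was given to 12, fewer than the 20.3 expected. For 71 proteins of the mitochondrial ribosome, the median was 0.04, within its range, though below it, at percentile 0.44, with random lists matched on length as well. None passed over the list alone, with 7 at an unadjusted p under 0.05 against 17.5 expected.

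Among chaperones, most subunits of the CCT chaperonin were lower by a small amount. Of the small heat shock genes, Hsp27, Hsp22 and Hsp23 were higher and Hsp26 lower. Neither group was a list of its own, and neither was tested. The median log2 change of 24 measured genes was -0.14, with 9 higher and 15 lower, below the range of 0.00 to 0.13 of matched random lists. None passed over the list alone, and 6 had an unadjusted p under 0.05 in the authors' deposited table, each with the lower mean at day 12, against 6.93 expected in either direction. Of these, CCT5, CCT8, CCT6 and CCT2 belong to the chaperonin that folds actin and tubulin, and CCT5 was at 145 and 107. The constitutive chaperone Hsc70-4 was at 1685 and 1293, and Hsp26 at 2825 and 2731. The sums of Hsp27, Hsp22 and Hsp23 had log2 changes of 0.46, 0.30 and 0.23, and none of them had a p under 0.05. The proteasome list, 32 genes, had a median of -0.01 against a range of 0.02 to 0.13, and lay within the range, at percentile 5.25, with single-transcript genes only. Prosalpha4, a subunit of the core particle, fell over the list alone, from 393 to 308 in the authors' deposited table.

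In glycogen and sugar metabolism, the median log2 change of 15 genes was -0.09, below the range of -0.03 to 0.14, with 7 genes higher and 8 lower; the median is the value of Pgi, and the next gene, Gapdh2, was at 0.01. Pfk, the committing step of glycolysis, fell over the list alone from 37.0 to 21.6, and AGBE, the glycogen branching enzyme, from 82.0 to 61.4 in the authors' deposited table. The lipid storage list had a median of -0.08 over 14 genes, just below its range, but it holds the chaperonin gene CCT1: without it the median of the other 13 was -0.04, within the range, and leaving out any other of the 7 lowest genes gives the same median. None passed over the list alone; the yolk receptor yl was at 335 and 192, with an unadjusted p of 0.0162 in the authors' deposited table. The nuclear pore and transport list had a median of -0.06 over 30 genes, below its range. Both lists lay within the range once random lists were matched on transcript length as well, at percentiles 6.13 and 3.15. Of the nuclear pore and transport genes, 3 fell and 2 rose over the list alone, most by little. Nup107 went from 30.8 to 22.8 in the authors' deposited table, and Nup43 from 81.8 to 80.4. Nup37, which also fell by its most abundant transcript, had a summed log2 change of 0.01. Histone genes had a median of -0.02 over 36 genes, below their range of -0.01 to 0.11 but within it, at percentile 2.64, with the most abundant transcript in place of the sum. None passed over the list alone, and 2 had an unadjusted p under 0.05, against 9.37 expected. Most of the listed genes are near-identical repeated copies, among which reads cannot be placed with certainty. His2Av, 1 of the 2 with a low p, is not such a copy, and was at 919 and 1085 in the authors' deposited table.

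Among cytosolic ribosomal proteins, some transcripts were lower while most of the group was level. Of 83 measured, 6 fell over the list alone and none rose, among them RpS20, RpL10Ab, RpL13A and RpLP0. RpL10Ab went from 1161 to 683 and RpL13A from 2172 to 1742 in the authors' deposited table. Over all transcripts tested, RpS20 alone was called; in every other list, 0 of the most abundant transcripts of the member genes were. The median of the list was 0.10, at percentile 72.9 of matched random lists, and 62 of the genes had a higher sum at day 12. Large differences that did not pass stood beside the decreases: besides RpS2, sta summed to 902 and 225 and RpS21 to 866 and 485. An unadjusted p under 0.05 was given to 19, against 26.2 expected.

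Single genes of the piRNA pathway, of meiosis and of autophagy were higher by little, in lists with level medians and with numbers of low p near those expected. In the piRNA pathway, which silences transposons in the germline, 5 of 26 rose over the list alone and none fell: armi, krimp, squ, Hen1 and piwi. In the authors' deposited table krimp went from 141 to 170 and piwi from 146 to 170. Among 38 genes of meiosis and the cell cycle, twe, polo, CycD and CycB rose and alphaTub67C fell over the list alone; polo, the kinase held back by mtrm, went from 360 to 405 in the authors' deposited table. Among 22 genes of autophagy and the lysosome, Vps15, Mitf, Atg17, Lamp1 and Atg13 rose over the list alone, though the summed value of Vps15 had a log2 change of -0.38. Lamp1 went from 375 to 421 in the authors' deposited table. The medians of these 3 lists were 0.09, 0.07 and -0.04, all within their ranges, with 8, 12 and 7 genes at an unadjusted p under 0.05 against 6.16, 10.3 and 5.08 expected. Of the autophagy and lysosome genes, 13 of 22 had a lower sum at day 12. Of 29 localized maternal and germ plasm genes, CycB rose and ovo and tsu fell over the list alone, and the median was -0.01. The summed log2 change of ovo was -0.18, against -0.91 for its most abundant transcript.

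**Figure D4:**
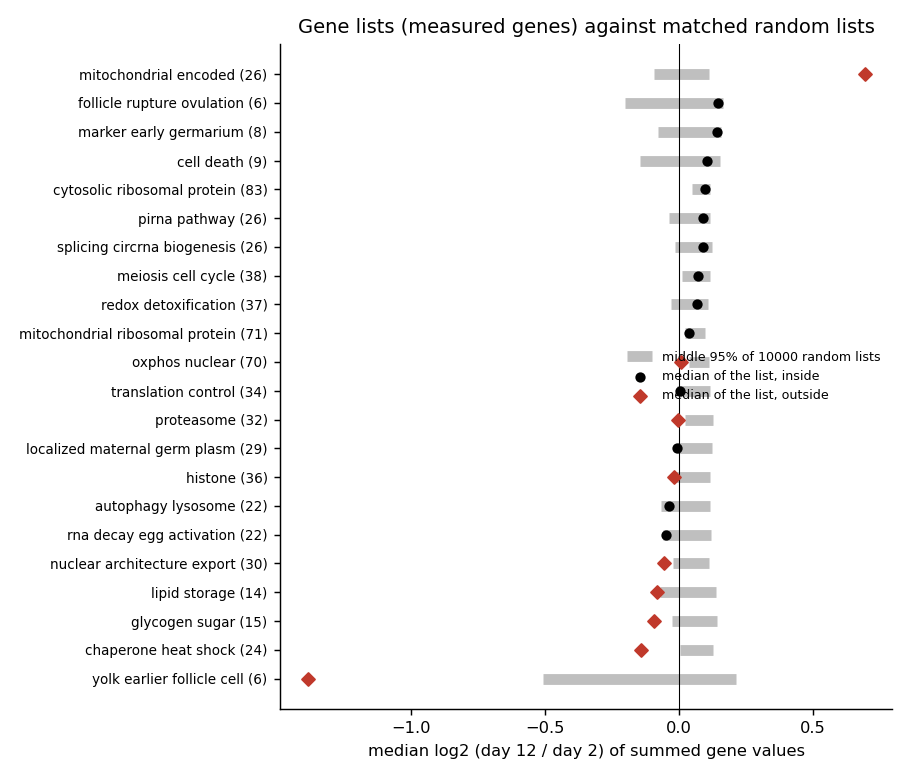
Median log2 ratio of day 12 to day 2 of the summed gene values (points) for 22 gene lists, with the number of measured genes in brackets; grey bars are the middle 95% of 10000 random lists matched on abundance. Red diamonds are the 9 lists outside their bar, 1 above (mitochondrial encoded) and 8 below.

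Yp1 and Yp2, which code for yolk proteins, and the chorion gene Cp15, all expressed in follicle cells, were lower. The yolk protein genes stood at low levels: Yp1 fell from 8.27 to 1.15 and Yp2 from 6.15 to 0.618 in the authors' deposited table, both over the list alone and neither over all transcripts. Yp3 summed to 6.77 at day 2 with a log2 change of -3.35, and did not pass. The list of yolk and earlier follicle cell genes had a median of -1.38 over 6 genes, below its range of -0.51 to 0.21. The list was split, with the 3 Yp genes lower and sn, bun and aop higher by 0.12, 0.08 and 0.17, so that the median lies between 2 groups; of the latter, sn passed over the list alone. Cp15, the 1 measured chorion gene of 22, and fs(1)M3, of 4 measured vitelline membrane genes, fell over their lists alone; with 1 measured gene, the p of Cp15 was in effect not adjusted. fs(1)M3, a product of the oocyte, went from 77.2 to 45.7 in the authors' deposited table. Genes of follicle rupture and ovulation had a median of 0.14 over 6 genes, within their range, with none past the list threshold and 1 at an unadjusted p under 0.05, and ecdysone genes gave 0 of 4.

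In cell death, Diap1, the inhibitor of caspases, fell over the list alone from 143 to 90.0 in the authors' deposited table, alone among 9 measured genes. In redox and detoxification, 37 genes, Sod3 and GstO1 rose and Trxr-1 and Irc fell over the list alone; Irc, a catalase-like enzyme, went from 11.8 to 4.16 in the authors' deposited table. Of 34 translation control genes, orb2 fell over the list alone, from 6.59 to 3.00 in the authors' deposited table. RNA decay and egg activation (22 genes) and splicing and circRNA biogenesis (26 genes) had 0 past the list threshold, with 6 each at an unadjusted p under 0.05. Of 4 measured immune genes, Rel and CG18067 rose over the list alone. The medians of the testable lists among these lay within their ranges. With the most abundant transcript in place of the sum, translation control and RNA decay lay below theirs, at percentiles 1.52 and 1.59.

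Markers of other tissues were nearly all outside the table. Of the fat body and blood cell markers and of the sperm, oviduct and spermatheca markers, 0 were measured; of the muscle markers 1, Tm1, at 116 and 145; of the neuron markers 1, Syx1A, at 3.08 and 4.47; and of the zygotic embryo markers 1, slam, at 14.5 and 12.5 in the authors' deposited table. Tm1 passed as the only member of its list. Such absence says little about other tissues, since few genes of the eggshell and of follicle rupture were listed either. Of the former, 1 of 22 chorion genes was measured, and of the latter 6 of 23. Of the early germarium markers 8 were measured, with a median of 0.14, within the range, and none passed over the list alone (1 at an unadjusted p under 0.05); nos, otu, vas and orb among them are maternal messages of the oocyte too.

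Few circular RNAs were called, and most were scarce. In the authors' deposited table, 3 of 2747 circRNAs had an adjusted p under 0.05. dme_circ_996 rose from 264 to 2248 (log2 change 3.10, adjusted p = 0.00014), which corresponds to 11 reads at day 2 and 123 at day 12, a ratio per total reads of 9.25 with an exact 95% binomial interval from 4.99 to 19.0. dme_circ_623 fell from 4362 to 1213 and dme_circ_973 from 2742 to 767, both with an adjusted p of 0.0459 in the authors' deposited table and with 233 against 65 and 143 against 40 reads. The intervals cover counting error only, not the spread between libraries. An unadjusted p under 0.05 was given to 61 circRNAs, 43 higher and 18 lower, fewer than the 137 that a uniform p would give, and the circRNA with the next lowest p had an adjusted p of 0.910.

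The most abundant circRNA, dme_circ_571, was at 44552 and 53831, and the 10 most abundant held 28.7% of the reads. At day 12, 2068 circRNAs lay above the lowest value of the table, and at day 2, 1885, with 1206 above it on both days. These numbers move with the total of back-splice reads, which was 1.21 times higher at day 12. Whether that total reflects sequencing depth or the amount of circRNA is unknown. Most circRNAs were scarce, with a median of 4 reads over the 6 libraries. Among the 259 circRNAs with at least 60 reads, 173 were higher at day 12 by the deposited values, with a median log2 change of 0.18. Per total reads, 125 were higher and 134 lower, with a median of -0.02. Because there is 1 value per day, no test of the totals or of the numbers detected was possible.

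**Figure D5:**
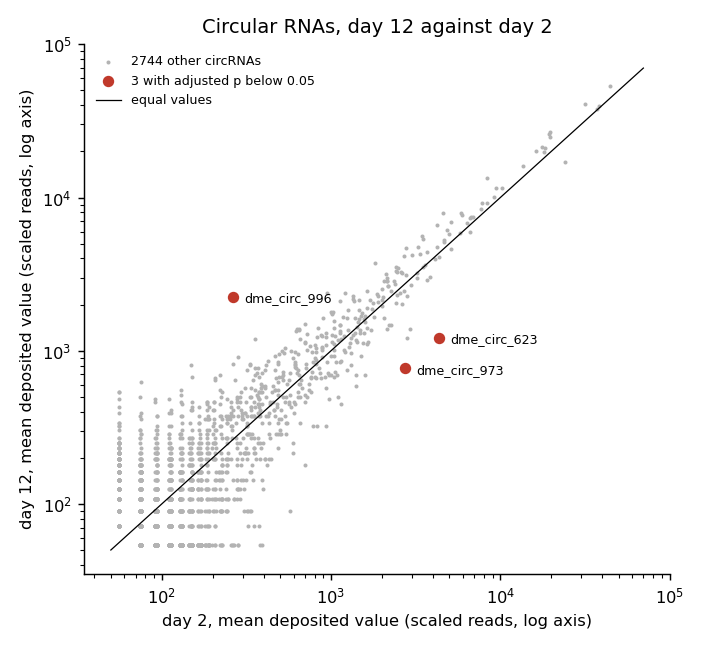
Deposited mean value at day 12 (vertical) against day 2 (horizontal) for 2747 circRNAs, both on log axes in scaled reads. Each grey point is 1 circRNA, the line marks equal values, and the 3 red points are the called ones: dme_circ_996 above the line, dme_circ_623 and dme_circ_973 below it. Rows of points at low values are steps of single reads.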

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

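The alternatives that select annotated transcripts, single-transcript genes, a mean of 10, the unadjusted p, the highest transcript, a pseudocount of 1, length-matched lists, the lipid list without CCT1 or reads per total were chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per day and no value per replicate number. For the same reason, the planned count models, size factors, limma fits, pseudocount for transcripts and circRNAs, left-out libraries, estimated correlations and counts of other splits of the samples were not run, nor was the filter of no low values, since the tables hold no further features. The comparison with host genes was not run for want of hosts. The 18 called transcripts became 121 at an adjusted p under 0.1 and 1629 at the authors' unadjusted mark, as looser thresholds do; each of the other transcript settings gave between 13 and 25. The 3 circRNAs became 61 at an unadjusted p, and were 3 in each planned setting. The 155 genes with a 2-fold difference became 49 with a mean of at least 10, since fewer genes enter, and 304 with the most abundant transcript in place of the sum; the cause was not tested. The 183 more circRNAs above the lowest value at day 12 became 106 when day 12 was thinned to the reads of day 2. Part of the difference thus goes with the larger number of back-splice reads at day 12. Whether that number reflects sequencing depth or more circRNA was not tested. The 9 gene lists outside their range became 5 with single-transcript genes, where 19 lists could be tested. Of the 9, 5 stayed outside their range in each alternative that could be run on them: yolk and earlier follicle cells (4 alternatives, with too few single-transcript genes for the other), and, in 5 alternatives, nuclear oxidative phosphorylation, mitochondrial RNAs, chaperones, and glycogen and sugar. Each mitochondrial gene has 1 listed transcript, so that choosing transcripts could not move that median. Of the called transcripts, Nct and eIF3l reversed when all transcripts of the gene were summed, to log2 changes of 0.27 and -1.001; of the other named transcripts of genes with several, 6 kept their sign and moved by less than 1.5-fold, 6 moved by more, and orb, not called, went from 0.25 to -0.06. The other 11 are the only listed transcripts of their genes, and those of GstT1 and trio have no finite log2 change, so that neither could be compared. Depth is unknown for linear RNA, so that no limit of detection can be given.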

Other observations

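All tests in this part, of RNA classes, of length and of explanations, were chosen after the results were seen. Some small nuclear RNAs, the RNA parts of the spliceosome and its relatives, were lower at day 12. Of 9 listed, 4 fell when the authors' p was adjusted over the class alone and 0 over all transcripts; of the 5 others, 4 had a lower and snRNA:U1:21D a higher value. In the authors' deposited table snRNA:7SK, which holds the elongation factor P-TEFb inactive, went from 7064 to 4743, and snRNA:U12 and snRNA:U11 of the minor spliceosome from 213 to 155 and from 141 to 61.0. Of 19 small nucleolar and Cajal body RNAs, 4 fell and 2 rose over the class alone; snoRNA:Tudor-SN-a went from 103 to 37.2, and snoRNA:Psi18S-1377b from 0.379 to 3.19 in the authors' deposited table. Of 110 other noncoding genes, 0 passed over the class and 18 had an unadjusted p under 0.05, among them lncRNA:CR40469, at 909 and 141, and lncRNA:CR34335, whose main transcript was at 1794 and 344 in the authors' deposited table.

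Change also followed transcript length. Over 3576 single-transcript genes with a mean of at least 1, the log2 change fell with length (Spearman rho -0.22, Pearson r -0.11 on log2 length, each with a permutation p of 1e-05, the smallest that 100000 permutations can give). This is a relation across genes, which are not independent replicates. The 716 shortest transcripts, up to 956 nt, had a median log2 change of 0.08, and the 715 longest, from 2975 nt, of -0.10. Abundance fell along with length, with a median value of 57.3 for the shortest and 24.4 for the longest. The relation was not adjusted for abundance, so the part of either cannot be told apart.

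The first pattern is large changes of single transcripts in genes with several. Of 144 transcripts with an unadjusted p under 0.05 and at least a 2-fold change in such genes, 82.6% had a summed gene change within 0.5 of 0 on the log2 scale. For most of them, a 2-fold change of the whole gene is argued against, since the median size of the summed log2 change was 0.23. Most gene sums were steady anyway, and no comparison with other genes was made, so smaller changes of whole genes are not excluded. The summed log2 changes of eIF3l, CG3967 and PlexB were larger, at -1.001, 0.87 and -0.67. What stays open is that reads may have been assigned to different overlapping transcripts on the 2 days, or that the follicles hold other isoforms, which predicts the same sums and was not tested. An example is bru1, a repressor of osk translation, with a transcript at 279 and 560 and another at 218 and 25.9 in the authors' deposited table, and a summed log2 change of 0.18.

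The second pattern is the split within the mitochondrial genome. A gain of short features at day 12 cannot be told apart from a change of the tRNAs themselves: 20 nuclear features of at most 200 nt had a median log2 change of -0.41, with 6 higher, but 1 of them was as short as the mitochondrial tRNAs. Within the mitochondrial genome, class and length run together. mt:ATPase8, an mRNA of 162 nt, rose by 0.57 (log2) without passing over the list alone, while the mRNAs that fell were 354 nt or longer. mt:ATPase6, at 675 nt, rose too. The tRNA that was lower, mt:tRNA:Gln-TTG, is an assembled transcript without a length. For mt:ATPase6 and mt:CoIII, the sum of both weighted by length changed by 0.034 on the log2 scale. Reads of 1 continuous message may have been counted to mt:CoIII at day 2 and to mt:ATPase6 at day 12, a candidate explanation. If so, the fall of mt:CoIII would be a matter of assignment. The 8 other mitochondrial mRNAs, all but mt:ATPase8 lower, had a median of -0.81, a fall that the sum of this pair did not share. The candidate explanation does not account for that difference and is not settled. An effect of follicle age on the 8 other mRNAs or on the tRNAs remains open and untested.

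The third pattern is the decrease of Yp1, Yp2 and Cp15. Less follicle cell RNA at day 12 cannot be told apart from other causes: the follicle rupture list had a median log2 change of 0.14, but of 6 genes known from follicle cells alone, 1 was measured, Ilp8, whose summed log2 change of 0.68 runs the other way. Follicles of earlier stages among those of day 2 cannot be excluded either, since the 7 other genes of the earlier follicle cell and vitelline lists had a median of 0.081, with 4 above and 3 below 0. That median lies between groups. The 3 below 0 were all vitelline genes, with summed log2 changes of -0.76 for fs(1)M3, -0.33 for fs(1)N and -4.57 for CG31928, the last at low values. The vitelline gene clos, at 0.09, and sn, bun and aop were above 0. Loss of leftover follicle cell messages with time may give the same values and was not tested. The labels do not say whether the days count time that follicles were held in the ovary.

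A last observation concerns the spread behind the circRNA values. For 110 circRNAs with enough reads, the day 2 library on the first step was set against the other 2 day 2 libraries. This log2 ratio had an SD of 0.38 across circRNAs, against 0.24 from counting alone. The log2 ratio of day 12 to day 2 had an SD of 0.42, against 0.16 from counting alone. The former ratio rests on fewer libraries than the latter, so spread between libraries enters the 2 SDs with unequal weight. The SDs thus do not tell whether the days differ by more than libraries of the same day.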
